A study of Homo sapiens with 8 samples.

How the data were processed

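The samples were 8 RNA samples of MDA-MB-231 cells given NET-DNA, 4 with a control construct and 4 with a guide against CCDC25, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, total RNA was linearly amplified, labelled with Cy3 and hybridised in 1 colour. Per the file headers and the submitters' processing notes, the authors scanned each array and extracted it with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give intensity per spot on a linear scale: a processed signal that was background-subtracted and spatially detrended but not scaled between arrays, and the median pixel intensity of the spot and its local background. They also hold other columns of 0 or 1 flags per spot, per the file headers, for outliers, saturation and signals well above background. A deposited series table holds values that the authors processed further, on a log2 scale. Its scale was found from the values: every column followed the log2 scanner signal of its own array (Pearson correlation across probes 0.999 to 1.00). All 8 columns had the same maximum of 17.01 and a median of 7.04, which is the pattern of quantile normalization, and knockout-minus-control differences correlated at 0.995 with quantile normalized scanner values. The table lists 33652 probes, and the 475 probes without a value there had a mean log2 scanner signal of 2.34 against 7.68 over all probes. Scale and direction are thereby settled, and values were not centred per gene. The step that made this table is not given in the sources used here.

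Each array had 43118 spots that were not controls. Spots marked as outliers, between 192 and 338 per array, were left out, and spots of one probe were averaged, leaving 34127 probes, of which 18 had every spot left out on some array. The main values were log2 of the processed signal minus the array's 75th percentile. The scanner files have no gene name column, so probes were named by accession through a RefSeq table of GRCh38.p14 without versions. It named 25771 of the 34127 probes with 19740 symbols, and 8356 probes kept the file's own identifier. The headers name hg19 for the array design, so no coordinates are printed, and the table served only for names and for the order of genes. For each gene name the probe with the highest mean over all 8 arrays was used. Genes well above background on at least 4 of 8 arrays were kept: 27269 of 27697, with 428 left out. Saturated spots were kept, of which there were 0.

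Knockout and control arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Python 3.11.15 and pandas 2.3.3 for reading files. Tests were two-sided and Benjamini-Hochberg adjusted, and a gene was called at an adjusted p under 0.05. The median SD between arrays was 0.15 in the control and 0.17 in the knockout group on the log2 scale. Where a probe was well above background on none of a group's arrays, the change is given as at least N-fold. Such a bound sets the brighter group's mean against, per array, the higher of the probe's own value and the lowest signal among probes well above background. Arrays were compared by 1 minus the Pearson correlation over all genes tested. Correlations between arrays were 0.995 to 0.997 within the control group, 0.993 to 0.998 within the knockout group and 0.962 to 0.976 between them. The mean distance between groups exceeded that within groups by 0.0267 (exact permutation test over 35 splits, one-sided, p = 0.0286, the smallest that 4 against 4 arrays allow).

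Before the data were examined, 33 gene lists were fixed and tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The results of 1 list that was not called, and of some named genes, are not given. Camera called 3 lists, and 0 after adjustment with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way without comparing them with other genes, called 16. Counts of called members were the same over all genes and adjusted over the list alone in 25 lists. They differed in 8, for which the text gives the second count or, in hypoxia (4 higher), cholesterol (14 higher), oxidative phosphorylation (6 lower), ribosomal protein (0 lower) and growth factor genes (14 lower), the counts stand here. In 11 lists, none of them called, the median, the mean and the test differed in sign. The named genes were set by a rule fixed at the same time: CCDC25; the 12 largest rises and falls among called, unsaturated genes with a symbol and fully separated groups; up to 4 called members with the smallest adjusted p per list; ILK, PARVB, PARVA, LIMS1, RAC1, CDC42, CGAS and STING1; and 5 neighbours of CCDC25 on each side. The largest changes among bright genes were added after the values were seen. A gene is called bright where its mean exceeds that of every E1A and ERCC probe, 22 control probes for spike-in transcripts; the labels do not say whether such transcripts were added.

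The fit and the list test were tested on simulated data for this comparison: 27269 genes with the real means and spreads. Of these, 200 were changed singly, and the remaining members of 1 list were raised 1.5-fold. Of 100 genes changed 1.5-fold, 50.0% were called, and of 100 changed 2-fold, 79.0%. Of 27030 unchanged genes 12 were called, and 1 seeded list was recovered with 0 others called. Far fewer genes were changed than the 14002 called in the real data, so the shares recovered need not hold there. The simulated genes were drawn independently of each other and without a slide effect. The simulation therefore cannot show how the list test behaves where members of a list move together. In the real data the ATF4 list had an estimated correlation of 0.26. Alternatives were quantile and median scaling, normexp with an offset of 50 followed by quantile normalization, the series table, other filters, other rules for probes, a replicate block, array weights, eBayes with trend and robust, each array left out in turn, and, added after seeing the data, bright genes only and cyclic loess. The plan named the mean spot signal for normexp; the files have no such column, so the median signal was used.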

Results

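Gene expression was measured in MDA-MB-231, an established triple-negative breast cancer cell line that metastasises readily in mice. The cells carried either a control construct or a guide RNA against CCDC25, and stable populations were obtained by puromycin selection. CCDC25 encodes a coiled-coil protein that has been described as a membrane receptor for the DNA of neutrophil extracellular traps, the chromatin webs that neutrophils release. Both populations received 0.5 ug of DNA from such traps (NET-DNA) by transfection, followed by 24 hours in culture. The comparison asks how the transcriptome of cells given this DNA differs when CCDC25 is disrupted. Cells without the DNA are not among the samples used here, so a response to the DNA itself was not measured.

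Total RNA from 4 control and 4 knockout samples was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 array per sample. The labels number the samples 1 to 4 in each group without naming separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The 75th percentile of the processed signal lay between 709 and 909 on the control arrays and between 1148 and 1546 on the knockout arrays. Between 91.1% and 95.4% of the spots were well above background on the control arrays, and between 98.6% and 99.0% on the knockout arrays. All 4 control arrays belonged to scan 1 and all 4 knockout arrays to scan 2, so slide, scan and group cannot be told apart in any value given here. The number of arrays limits the precision of every value.

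CCDC25 itself was lower on every knockout array. Its log2 signal relative to the array's 75th percentile was 0.51, 0.58, 0.62 and 0.62 on control arrays 1 to 4 and -1.11, -0.98, -0.94 and -0.96 on knockout arrays 1 to 4. The group means were 0.58 ± 0.05 and -0.997 ± 0.079 (SD, n = 4 arrays each), a log2 fold change of -1.58 (SE 0.07, limma adjusted p = 2.45e-06). This left 33.4% of the control signal. By limma's moderated statistic CCDC25 ranked 1 among all decreases, and by fold change it ranked 51. The files do not say whether the probe (A_23_P71300) lies inside or outside the part that the guide cuts, and a transcript with a small deletion can persist, so the level checks the labels of the arrays but not the loss of the protein.

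**Figure D1:**
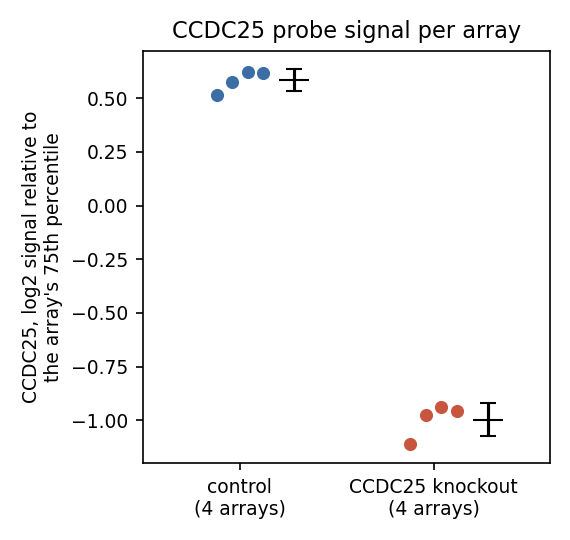
Log2 signal of the CCDC25 probe relative to the 75th percentile of each array (y axis) in the control and knockout groups (x axis), with 1 point per array and the mean ± SD of 4 arrays beside it. Control arrays sit between 0.51 and 0.62 and knockout arrays between -1.11 and -0.94.

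In knockout cells, 21 of 35 ATF4 and unfolded protein response genes were lower and 4 higher, 20 of 33 ribosome biogenesis genes were lower and 0 higher, and 20 of 25 antigen presentation genes were higher and 0 lower. These 3 lists were called by camera with a preset correlation. All 3 calls were lost by camera with an estimated correlation (adjusted p = 0.949, 0.949 and 0.491). CHAC1, a glutathione-degrading enzyme induced by the stress transcription factor ATF4, was 3.18-fold lower on the brighter of its probes. The inflammatory prostaglandin synthase PTGS2, on a probe dimmer than the brightest spike-in control probe, was 4.15-fold lower. HLA-C, which encodes a class I antigen-presenting molecule, was 2.76-fold higher, and PSMB9, a subunit of the immunoproteasome, was 1.98-fold higher. In all, 14002 of 27269 genes tested passed an adjusted p of 0.05 in limma, 6512 of them higher and 7490 lower in the knockout arrays. That balance turned with the median of each array as the scale (7469 higher and 6792 lower), with cyclic loess (8944 and 8094), without control replicate 2 (6355 and 5783) and without knockout replicate 1 (7010 and 6898). Of the 14002 genes, 2641 differed at least 2-fold, 1905 higher and 736 lower. In 12980 genes (47.6%) all 4 arrays of one group lay above all 4 of the other, where chance gives 2.86%. All 168 called genes among the 177 named by the rule for named genes and its later addition were separated so. The rule required this for the largest changes and mostly picked list members by small adjusted p-values, so the 168 add no support. Changes of single genes are given below as log2 fold changes, knockout minus control, unless a fold is stated.

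This large number of called genes carries 2 measured limits. Probes for spike-in transcripts, which no human gene supplies, differed as well: 12 of 22 such control probes passed the same threshold, with log2 fold changes between -1.75 and 0.50. Of the 12, 11 were lower, a direction that depends on the scale. Before scaling, the median E1A signal was 63.7 to 72.1 on control arrays and 82.1 to 110.4 on knockout arrays. The 75th percentile used as the scale was 1.64-fold higher on the knockout arrays. Separate probes of one gene also moved with little relation to each other, with a Pearson correlation across 2026 genes of 0.27 (Spearman 0.26) even where both probes were brighter than every spike-in control probe. Genes are not independent replicates. Among the 12772 genes above that brightness, 6385 were called and 591 differed at least 2-fold, 537 higher and 54 lower. Many genes named below lay under that brightness, where 2 probes of one gene correlated at 0.01 across 1721 genes. Among them were PARVB, ITGA1, TLR3, ZBP1, RSAD2, PTGS2, IL1A, FOSB, KRT5, CDH3, MMP2, MMP3, MMP9, SPP1, COL1A1, AMOTL1, CLSPN, TP53INP1, HSPA6 and HSPA1A. Also under it were EPHX2, MFAP5, MS4A1, the named neutrophil, endothelial, kidney and neuronal markers, and the 12 largest falls by the fixed rule.

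**Figure D2:**
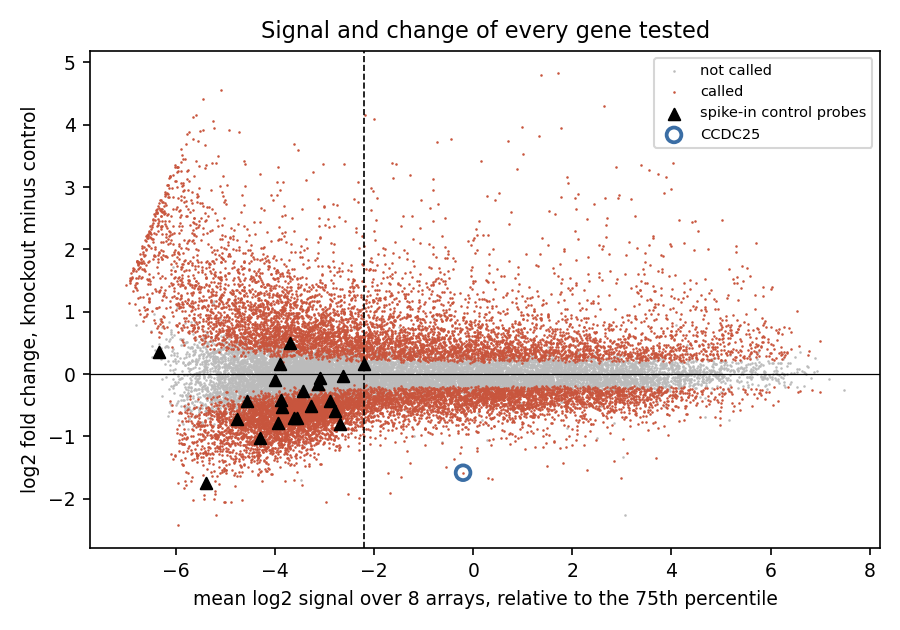
Mean log2 signal over 8 arrays relative to the 75th percentile (x axis) against the log2 fold change, knockout minus control (y axis), with 1 point per gene tested and triangles for the 22 spike-in control probes. The dashed line marks the brightest of those control probes at -2.21; CCDC25, circled, lies at -1.58.

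The antigen presentation list was called higher by camera with a preset correlation of 0.01 (adjusted p = 3.97e-05). Of its 25 measured members, 20 were higher, 0 were lower and 5 did not pass. Its median log2 fold change was 0.48. Adjusted over the list alone, 20 were higher and 1 was lower. With an estimated correlation the call was lost (adjusted p = 0.491). HLA-C rose by a log2 fold change of 1.46 (SE 0.11, adjusted p = 1.57e-05) and HLA-G, a non-classical class I gene, by 1.06 (SE 0.10, adjusted p = 4.60e-05). PSMB9 rose by 0.99 and HLA-E, the ligand of an inhibitory receptor on natural killer cells, by 0.72. HLA genes are close in sequence and their probes can share signal. Of the 14 members outside the HLA family, 11 were higher and 0 lower, with a median of 0.47.

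The list of ATF4 targets and unfolded protein response genes was called lower (camera adjusted p = 5.36e-04). Of 35 measured members, 21 were lower, 4 were higher and 10 did not pass, with the same counts when adjusted over the list alone and a median log2 fold change of -0.51. With an estimated correlation the call was lost (adjusted p = 0.949). CHAC1 fell by 1.67 (SE 0.11, adjusted p = 1.02e-05), and by 0.47 on its second, dimmer probe. The cystine transporter SLC7A11 stood at -1.40 (SE 0.15, adjusted p = 1.30e-04) and the pseudokinase TRIB3 at -1.10 (SE 0.12, adjusted p = 1.39e-04). SESN2, a stress-induced regulator of mTORC1, went the other way with a log2 fold change of 2.81 (SE 0.31, adjusted p = 1.46e-04). Its level spread widely within the knockout group, from 3.76 on array 3 to 5.07 on array 4. Other large rises, such as those of ITGAM and HDAC5, were likewise lowest on array 3 and highest on array 4 of that group.

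The ribosome biogenesis and MYC target list was also called lower (camera adjusted p = 5.36e-04). Of 33 measured members, 20 were lower, 0 were higher and 13 did not pass, again with the same counts when adjusted over the list alone, and the median log2 fold change was -0.27. With an estimated correlation the call was lost (adjusted p = 0.949). Spermidine synthase SRM fell by 0.81 (SE 0.10). The ribosome assembly factors RRP9, RRP12 and MRTO4 had log2 fold changes of -0.60, -0.56 and -0.52, each with an SE of 0.08. The adjusted p-values of these 4 genes lay between 2.20e-04 and 8.14e-04.

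**Figure D3:**
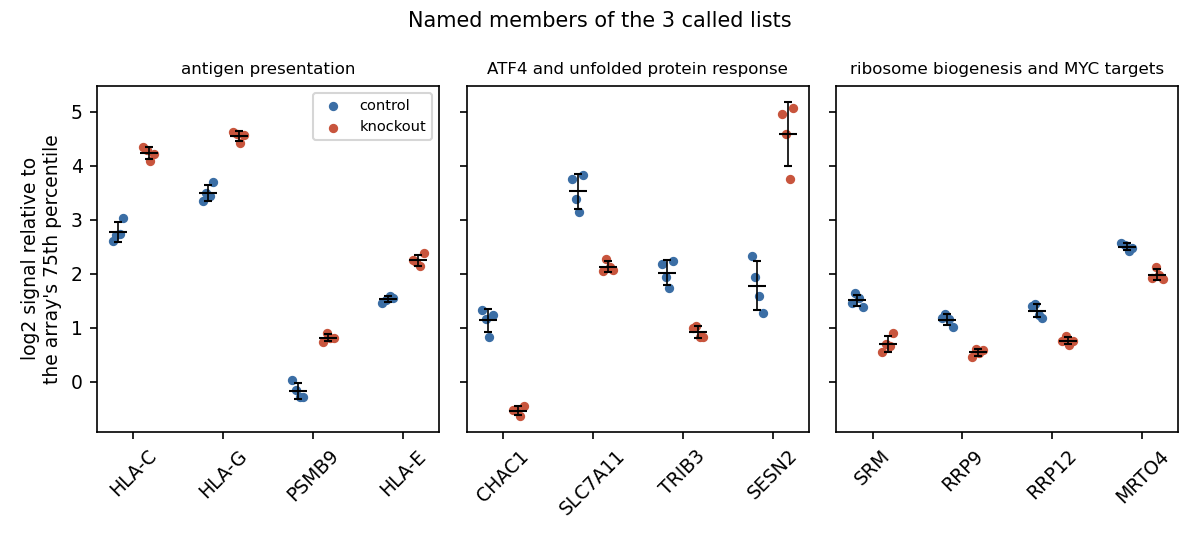
Log2 signal relative to the 75th percentile of each array (y axis) for the 4 members with the smallest adjusted p in each of the 3 lists called by camera (x axis), with 1 point per array, control in blue and knockout in red, and bars for the mean ± SD of 4 arrays. SESN2 rises where the other named members of its list fall, and its knockout arrays spread from 3.76 to 5.07.

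None of the lists linked to CCDC25 and to DNA sensing was called. CCDC25 has been reported to signal through integrin-linked kinase and beta-parvin. The gene of that kinase, ILK, had a log2 fold change of -0.13 (SE 0.12, adjusted p = 0.377), and PARVB, which encodes beta-parvin, 0.26 (SE 0.20, adjusted p = 0.307), with only 2 control arrays well above background. PARVA stood at 0.04 (adjusted p = 0.723), so a difference was not detectable for these 3 genes at this precision, although with array weights ILK was called lower (-0.26). LIMS1, the adaptor PINCH1 that binds ILK, fell by 0.48 (adjusted p = 0.00135). RAC1 fell by 0.49 (adjusted p = 0.00549). CDC42 was higher by 0.46 (adjusted p = 0.00314), but both of its other probes, with log2 fold changes of -0.14 and -0.13, did not pass, and its call was lost with the mean over its probes.

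In the list of ILK, parvin, integrin and focal adhesion genes, 11 of 37 members were higher and 7 lower (camera adjusted p = 0.594), or 9 and 9 with quantile normalization and 9 and 10 with the series table. PAK2, a kinase downstream of RAC1 and CDC42, rose by 0.97, the talin gene TLN2 by 1.17 and the collagen receptor subunit ITGA1 by 1.38, while the integrin activator FERMT2 fell by 0.77.

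Of the cytosolic nucleic acid sensing list, 2 of 20 members were higher and 5 lower (adjusted p = 0.730), or 5 and 5 with cyclic loess. The DNA sensor CGAS fell by 0.60 (SE 0.09, adjusted p = 5.81e-04), and its adaptor STING1 stood at 0.05 (SE 0.08, adjusted p = 0.655). ENPP1, which degrades the messenger cGAMP, fell by 0.84, with its second probe at -0.29 and not called, the endosomal RNA sensor TLR3 rose by 0.85 and the nucleic acid sensor ZBP1 fell by 0.88. Interferon-stimulated genes went both ways, with 12 of 38 higher and 4 lower (adjusted p = 0.283), or 10 and 4 adjusted over the list alone. OAS2 rose by 0.94 and IFIH1, the RNA sensor MDA5, by 0.53. RSAD2 and ISG15, both strongly interferon-inducible, were lower, at -0.95 and -0.50.

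The inflammatory cytokine and NF-kB list had 16 of 33 members lower and 9 higher (adjusted p = 0.324). Besides PTGS2 (-2.05, SE 0.15, adjusted p = 1.77e-05), the neutrophil chemoattractant CXCL2 fell by 1.23 and IL6 fell by 0.89. The second probe of CXCL2 stood at -0.57. IL1A, which encodes interleukin 1 alpha, fell by 1.72 (SE 0.19, adjusted p = 1.28e-04). CSF1 was higher by 1.27 on its brightest probe, whereas its second probe stood at -0.20 and its dimmest fell by 0.87, and its call was lost with the mean over its probes. Immediate early and AP-1 genes had 16 of 35 lower and 4 higher (adjusted p = 0.0580), among them EGR1 at -1.19, ZFP36 at -0.91, NR4A2 at -0.87 and FOSB at -0.72; the second probe of NR4A2 stood at -0.22 and was not called. NRF2 and antioxidant genes had 16 of 28 lower and 5 higher (adjusted p = 0.0580), and camera called this list lower with quantile normalization, the series table, normexp and the mean over probes. Immediate early genes were called lower with normexp and the mean over probes. Both lists were also called lower without control replicate 2 (medians -0.37 for NRF2 and -0.26 for immediate early genes), control replicate 3 (-0.40 and -0.27) or knockout replicate 1 (-0.36 and -0.20). The aldo-keto reductase AKR1C1 fell by 1.67 (second probe -0.62), the ferritin light chain FTL fell by 0.97 and the transporter ABCC2 fell by 0.75. Probes of the ferritin genes differed: a second FTL probe stood at -0.09, and FTH1, the heavy chain, had log2 fold changes of 1.25, -0.16 and 1.55 on its 3 probes.

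None of the lists of migration and metastasis was called. Mesenchymal markers had 8 of 27 higher and 8 lower (adjusted p = 0.967), with the collagens COL6A1 and COL5A1 higher by 1.22 and 1.14, PDGFRB by 0.94, and the transcription factor SNAI1 at -0.70. Epithelial markers had 5 of 25 higher and 9 lower (adjusted p = 0.760), or 6 and 6 with the median of each array as the scale. The claudin CLDN3 and the cadherin CDH3 rose by 0.65 and 0.78, and EPCAM fell by 0.46. The keratin KRT5 was called higher but was well above background on 0 control arrays, and its call was lost with normexp. Among matrix proteases and inhibitors, 9 of 29 were higher and 7 lower (adjusted p = 0.592). The gelatinases MMP2 and MMP9 rose by 2.20 and 1.104 and the stromelysin MMP3 fell by 1.45, all on probes dimmer than the brightest spike-in control probe. ADAM8, on a brighter probe, rose by 0.88. In the list of lung and bone metastasis genes known from this cell line, 11 of 27 were lower and 3 higher (adjusted p = 0.210), including osteopontin SPP1 at -1.03 and the inhibitor of differentiation ID1 at 0.72. TGF-beta targets had 5 of 26 higher and 5 lower (adjusted p = 0.967), with COL4A1 at 0.93, COL1A1 at 0.92 and the SMAD repressor SKIL at -0.45. YAP/TAZ targets had 9 of 24 higher and 10 lower (adjusted p = 0.967), or 7 and 5 with the median of each array as the scale. CRIM1 stood at 1.57, ANKRD1 at -0.89, IGFBP3 at -0.74 and AMOTL1 at 0.89, with its other probe at -0.35 and not called.

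**Figure D4:**
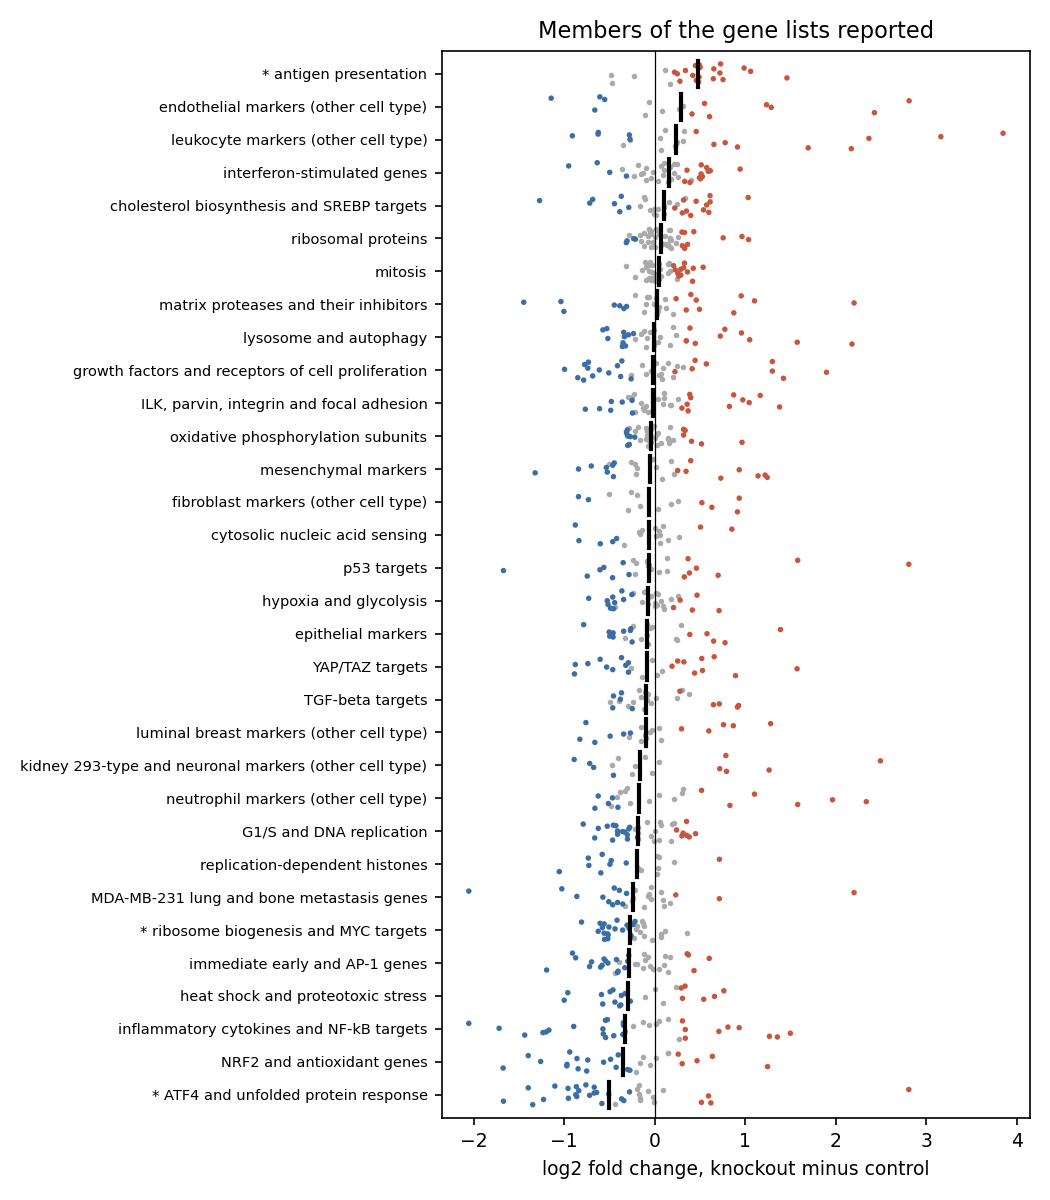
Log2 fold change, knockout minus control (x axis), of every measured member of the gene lists reported here (y axis, ordered by median), with called members in red (higher) or blue (lower), other members in grey, and a black bar at each median. An asterisk marks the 3 lists called by camera, whose medians are 0.48, -0.27 and -0.51.

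Proliferation and growth lists were not called. Mitosis genes had 12 of 39 higher and 0 lower (adjusted p = 0.226), or 10 and 0 adjusted over the list alone. The kinesins KIF4A and KIF23 stood at 0.54 and 0.43, ANLN at 0.42 and DLGAP5 at 0.36; the call of KIF23 was lost with the mean over its probes, and the second probe of KIF4A stood at 0.18 and was not called. G1/S and replication genes had 16 of 38 lower and 7 higher (adjusted p = 0.289), or 8 and 6 with the median of each array as the scale. Among them were RRM2, a subunit of ribonucleotide reductase, at -0.79, CLSPN at -0.66, POLA2 at -0.62 and RFC3 at -0.52. Replication-dependent histones had 8 of 17 lower and 1 higher (adjusted p = 0.283). Their mean log2 signal was -0.11 on knockout array 1, 0.23 to 0.36 on the other knockout arrays and 0.35 to 0.57 on the control arrays. The median log2 fold change of these histones was -0.19, and -0.18 without knockout replicate 1. The linker histones H1-4 and H1-2 stood at -1.05 and -0.59, H2BC8 at -0.48 and H3C10 at 0.72, the last not called with the mean over its probes. Growth factors and receptors had 8 of 34 higher and 13 lower (adjusted p = 0.730), or 10 and 10 with the median of each array as the scale. The cell cycle kinase CDK6 fell by 0.85 and the growth factor NRG1 fell by 0.77. TGFA rose by 1.30, while its second probe stood at -0.21.

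Stress and metabolic lists beyond these were not called either. p53 targets had 7 of 26 higher and 7 lower (adjusted p = 0.967), with the stress cytokine GDF15 at -1.67, TP53INP1 at 1.58 and the pro-apoptotic BBC3 at -0.74. Heat shock genes had 12 of 22 lower and 6 higher (adjusted p = 0.592), or 6 and 6 with the median of each array as the scale, with DNAJB4 at -0.999, HSPA6 at -0.96, HSPB1 at 0.77 and HSPA1A at 0.66. HSPB1 was not called with the mean over its probes. Hypoxia and glycolysis genes had 10 of 33 lower and 5 higher (adjusted p = 0.592), or 7 and 6 on that scale, with P4HA2 at -0.73, LOX at -0.52, BNIP3 at -0.49 and adrenomedullin ADM at 0.71. Cholesterol and SREBP genes had 12 of 33 higher and 7 lower (adjusted p = 0.324). Mevalonate kinase MVK stood at 0.61 and DHCR7 at 0.60, and SREBF1 at 1.03 against -0.73 on its second probe, its call lost with the mean of both.

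Oxidative phosphorylation subunits had 6 of 39 higher and 8 lower (adjusted p = 0.967), with COX5A at 0.97, ATP5MC3 at 0.52, SDHC at 0.32 and NDUFS1 at -0.31. The balance of the list turned with the scale: 7 higher and 0 lower with the median of each array, where NDUFS1 was not called, 5 and 13 with quantile normalization or the series table, and 5 and 16 with normexp; SDHC was not called with the mean over its probes. Ribosomal proteins had 9 of 46 higher and 4 lower (adjusted p = 0.283), a balance that turned to 5 higher and 22 lower with quantile normalization and with the series table, to 4 and 22 with normexp and to 7 and 14 with cyclic loess. RPS12 and RPLP1 stood at 0.97 and 0.76 and RPS24 at 0.33, the last of which was not called with quantile normalization, normexp or the series table. RPL7 stood at 1.04, and its other probes at -0.19 and -0.47; its call was lost with the mean over its probes. Lysosome and autophagy genes had 9 of 33 higher and 10 lower (adjusted p = 0.730), or 11 and 3 with the median of each array as the scale. The proton pump subunit ATP6V1A stood at 2.18, CTSA at 1.58 (second probe 0.56), GAA at 1.05 and TFE3 at 0.78.

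In the main setting, none of the lists of markers of other cell types was called. Leukocyte markers had 9 of 24 higher and 5 lower (adjusted p = 0.0826; called higher with normexp and, at a median of 0.35, without knockout replicate 1), led by MS4A1, a B cell antigen that was not well above background on the control arrays and at least 3.001-fold higher in the knockout arrays. ITGAM, a myeloid integrin, was 8.96-fold higher and FCER1G 5.16-fold. Neutrophil markers had 6 of 22 higher and 5 lower (adjusted p = 0.730), with CXCR2 at least 2.24-fold higher, DEFA4 at least 2.23-fold higher and CSF3R 2.99-fold higher. Endothelial markers had 7 of 16 higher and 4 lower (adjusted p = 0.226), with SOX18 7.02-fold, MMRN2 2.36-fold, CDH5 1.52-fold and EMCN at least 2.04-fold higher. Fibroblast markers had 4 of 14 higher and 2 lower (adjusted p = 0.730), including DPT at 0.63 and MFAP5 at 0.52. Luminal breast markers had 5 of 20 higher and 6 lower (adjusted p = 0.730), or 5 and 4 with the median of each array as the scale, with the trefoil factor TFF3 at 1.28, CA12 at -0.83, AGR2 at -0.66 and XBP1 at -0.76. Kidney and neuronal markers had 5 of 16 higher and 4 lower (adjusted p = 0.967), or 3 and 7 with quantile normalization, with SNAP25 at 2.49 and INA at 1.27. PAX2 and NEFH stood at -0.72 and -0.67, their second probes rose, and the means over their probes were 0.37 and 0.03, not called.

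The largest single changes were rises. FAM178B was 28.3-fold higher, from -0.70 ± 0.22 to 4.12 ± 0.62 (SD, n = 4, limma adjusted p = 5.35e-06), but its second probe rose by a log2 fold change of only 1.18 and its dimmest fell by 0.62. LINGO3 was 17.8-fold higher, the small GTPase RAB38 15.6-fold, the histone deacetylase HDAC5 15.4-fold, the potassium channel KCNH7 13.6-fold and the serine protease PRSS56 13.4-fold. The other 6 of the 12 largest rises were not well above background on any control array, so only a bound can be given. BRSK1 was at least 5.50-fold higher, PCARE at least 4.65-fold, the kallikrein KLK10 at least 3.79-fold, SLCO5A1 at least 3.18-fold, NETO2 at least 3.12-fold and MS4A1 at least 3.001-fold. Of the 1905 rises of at least 2-fold, 632 had 0 control arrays well above background.

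The largest falls were smaller. Among genes well above background on all 4 knockout arrays, PTGS2 was followed by FGFRL1, a decoy receptor for fibroblast growth factors, 3.98-fold lower (log2 fold change -1.99, SE 0.11), then VLDLR-AS1 at 3.81-fold, ZIM3 at 3.79-fold, the inflammasome regulator CARD18 at 3.46-fold, GJA9 at 3.43-fold and IL1A at 3.29-fold. TAAR6, FABP2 and KCNG2 had log2 fold changes of -2.42, -2.03 and -1.75 with 1 knockout array well above background, and SLC60A1-AS1 and ADAM5 -2.05 and -1.94 with 3. Among genes brighter than every spike-in control probe, a set chosen after the values were seen, the largest falls were AKR1C1 at 3.19-fold, GDF15 and CHAC1 at 3.18-fold each, the protease-activated receptor F2RL2 at 3.005-fold and CCDC25. Next came the cell cycle kinase CDK4 at 2.91-fold, RPIA at 2.79-fold, the small nucleolar RNA SNORD3B-1 at 2.67-fold, SLC7A11 at 2.63-fold, asparagine synthetase ASNS at 2.54-fold, GABPB1 at 2.40-fold and heme oxygenase HMOX1 at 2.39-fold. Second probes of AKR1C1, CHAC1 and GABPB1 fell less, with log2 fold changes of -0.62, -0.47 and -0.43. The call of SNORD3B-1 was lost with robust moderation and without control replicate 1, 3 or 4 (-1.39, -1.43 and -1.38). Its size rested on knockout replicate 1, at -0.47 against 1.41, 1.54 and 1.92 on the other knockout arrays: without it the log2 fold change was -0.90, under 2-fold, and still called. Its second probe stood at -0.76 and was not called. The largest rises in that set after PRSS56 were the prostaglandin receptor PTGFR at 13.2-fold, IL17RE at 11.5-fold, CPB1 at 10.7-fold, OPN3 at 10.4-fold, MAGEA8 at 10.4-fold and MCEMP1 at 10.3-fold. The second probes of PTGFR and OPN3 had log2 fold changes of -0.05 and 0.48.

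Genes next to CCDC25 on its chromosome were measured to look for changes around the targeted locus. Of 10 neighbours, 5 on each side, 1 was higher and 4 were lower. Over all genes tested 51.3% were called, so the neighbours were called about as often as other genes. SCARA3 was higher by 0.69, with its second probe at -0.33, and its call was lost with the mean of both. CLU, ELP3, EPHX2 and NUGGC stood at -0.34, -0.29, -1.005 and -0.35, EPHX2 on a probe dimmer than the brightest spike-in control probe. ELP3 and NUGGC were not called with the median of each array as the scale. ELP3 was also not called without control replicate 1 or 2 (-0.23 and -0.27) or without knockout replicate 2, 3 or 4 (-0.30, -0.28 and -0.24). These 4 falls were all smaller than that of CCDC25. The other neighbours were not called; of them CHRNA2, PTK2B, SCARA5 and ESCO2 each passed in at least 1 other setting.

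**Figure D5:**
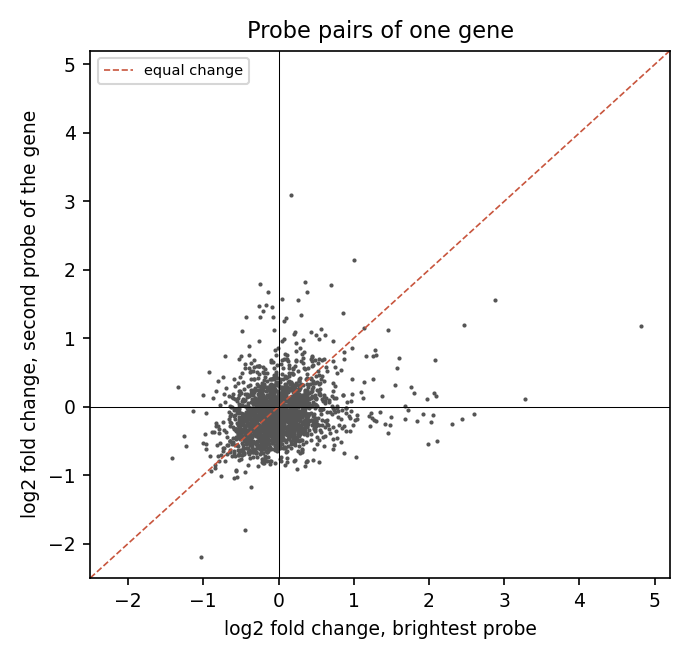
Log2 fold change, knockout minus control, of the brightest probe (x axis) against the second probe (y axis) of each of 2026 genes with 2 probes brighter than every spike-in control probe, with 1 point per gene and a dashed line where both changes are equal. Where the brightest probe rose at least 2-fold the second probe had a median of -0.01, and the correlation across genes is 0.27.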

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

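The tests of 2 probes with the same accession, of the shared deviation of rising probes and of the slide batch, and the spread used to judge second probes of the lists, were chosen only after the results were seen. Dixon's test marked 14 of 434 groups of 4 arrays, where chance marks about 1 in 20. On the log2 scale, knockout array 1 stood apart for CARD18 (-6.62), WASF3 (0.68), CRIM1 (2.76), H1-4 (-0.90) and LOX (-1.79). Control array 2 stood apart for MMP9 (-3.67), ID1 (4.96) and SDHC (3.85), control array 4 for SNAI1 (0.26), RFC3 (1.22) and BNIP3 (3.32), control array 1 for COL4A1 (-1.81) and control array 3 for NUGGC (-1.08). Knockout array 2 had a median signal of 173.8, below 205 to 209 on the other 3. Outside the gene probes, the bright corner spots, which orient the scanner's grid, were 15.8-fold brighter on the knockout arrays, while the 75th percentile of the signal was 1.64-fold higher. Also outside them, 12 spike-in control probes were called on the scaled values, 11 lower and 1 higher.

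The first pattern is that 14002 genes, 51.3% of those tested, were called. A chance split of the arrays is argued against for this count and for the 2641 genes changed at least 2-fold. For each, only 1 of 35 splits of the 8 arrays, the real one, gave as many, and the highest of the others gave 0. With 35 splits this is the strongest result such a test can give. The real split is also the split by scan, and the arrays may be technical replicates. A spatial pattern on the slides is argued against, since bright genes on neighbouring spots had a correlation of 0.00171. Signal specific to single probes may contribute and stays open, since bright probe pairs of one gene correlated at 0.266 (bootstrap 95% interval 0.217 to 0.318) and those of one accession at 0.255 (0.203 to 0.304), above the 0.2 set for that cause but below the 0.5 set against it, where the spread between arrays alone would allow 0.954. The knockout of CCDC25 and a slide or scan batch cannot be told apart, because 0 scans held arrays of both groups.

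The second pattern is that rises of at least 2-fold outnumbered falls, 1905 to 736. Among dim genes, with 1368 rises, the data are consistent with signal specific to single probes: 2 dim probes of one gene correlated at 0.0117 (interval -0.040 to 0.063), and 10 of 63 such rises were matched on the second probe. Among bright genes, with 537 rises, the rising probes deviated together within the knockout group, with a median correlation over pairs of 0.504 against 0.027 to 0.113 in 100 random draws of bright genes. It was 0.770 among the 109 that rose at least 4-fold, which include SESN2, ITGAM, HDAC5 and ATP6V1A. Of the 537 genes, 52 had a second bright probe, and 6 of those second probes rose 2-fold. Second probes carried 0.182 (interval 0.087 to 0.297) of the first probes' difference between knockout arrays 4 and 3. A factor of single probes predicted under 0.25 and a change of whole transcripts at least 0.5. These 2 arrays had the highest and lowest mean deviation of the rising genes (0.238 and -0.227), and first probes were selected for their rise. Both can bias the ratio low. Between the groups, the median log2 fold change was 1.48 on first probes and -0.01 on second probes. Within that limit, an interval wholly under 0.5 argues against a change of whole transcripts in these 52 genes as a set. Rising genes without a second bright probe were not covered. The interval crosses 0.25, so a factor of single probes stays open, as do the slide batch, the knockout of CCDC25 and a change of single isoforms, which was not tested.

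The third pattern is the direction of the 3 called lists. Dim probes are argued against where a list also held dim members. The bright members alone had medians of -0.545 (ATF4 and unfolded protein response, 32 of 35 members) and 0.498 (antigen presentation, 18 of 25). All 33 ribosome biogenesis members were bright, so their median of -0.266 is that of the whole list and no dim probe entered it. Cross-hybridisation among HLA genes as the whole cause is also argued against, since the other members lay 0.541 above the median of all genes. Second bright probes lay -0.678 from the median of all such probes for ATF4 genes, with 5 probes of 4 genes. Of these probes 4 were called lower and 1 higher, which argues against single-probe signal in those genes but rests on few. For antigen presentation (0.817, 4 probes of 3 genes, 4 called higher) and ribosome biogenesis (-0.105, 6 probes) they did not decide. That verdict used the spread chosen after the results were seen, whereas antigen presentation met the rule written before. That rule compared second probes with the list's own shift. Ribosome biogenesis met it with the shift taken against all genes (-0.197) but not with the list's median (-0.266). Chance could not be excluded for the count of 3 lists: 30 of 35 splits gave at least as many, the highest of the others 18, which points to structure among the arrays that moves genes of one list together. A slide batch and the knockout of CCDC25 both stay open for all 3.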

How the results depend on the processing

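The bright-only and cyclic loess settings were chosen after seeing the data. CCDC25 stayed called in all 21 other settings (-1.60 to -1.43), and array distances kept their direction in all 18 that gave one. Called genes numbered 11724 to 17573 in every setting but one: 7384 with bright genes only, where fewer were tested. Genes changed at least 2-fold fell from 2641 to 599 with normexp (553 higher, 46 lower) and, with fewer genes tested, to 593 with bright genes only (537 higher, 56 lower) and 1638 with detection on all 8 arrays (975 higher, 663 lower). Their main split of 1905 higher and 736 lower became 2150 and 446 with cyclic loess, 2055 and 433 without knockout replicate 1, and 1758 and 1085 without knockout replicate 4. Camera called 0 lists with an estimated correlation (2 at an unadjusted p under 0.05, 16 by fry), 6 with normexp, 5 with the mean over probes, 4 with quantile normalization and with the series table, and 3 to 6 when 1 array was left out (6 without knockout replicate 1, 5 without control replicate 2 or 3). The lists added were NRF2 genes wherever over 3 were called, immediate early genes where 5 or 6 were called, and leukocyte markers where 6 were called. With the mean over probes, PAX2 (0.37) and NEFH (0.026) reversed, since their second probes oppose the first. For the other changes the cause was not tested. Across all settings, named genes lost their call in 25 instances and gained it in 13; 50 uncalled values changed sign without being called in either setting. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.22, 0.11, -0.05 and -0.43, and not every array correlated best with its own number. With a replicate block, 12063 genes were called, 2640 at least 2-fold, and 3 lists. The planned slide block was not run: each scan held 1 group, so its effect equals the group difference. Signal over background limits the dim genes, 14497 of those tested.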

Other observations

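The members of the stress list beyond the fixed rule and the probe series comparison were chosen only after their values were seen. In the ATF4 and unfolded protein response list, the transcription factors DDIT3 (CHOP) and ATF4 had log2 fold changes of -1.23 and -0.58, the amino acid transporters SLC3A2 and SLC7A5 -0.96 and -0.67, and PHGDH, an enzyme of serine synthesis, -0.67. The endoplasmic reticulum chaperone HSPA5 stood at -0.72, HERPUD1 at -0.86 and DNAJB9 at -0.95. The 4 higher members were SESN2 (2.81), ATF5 (0.62), CALR (0.52) and HSP90B1 (0.60), the last with another probe that opposed it. MYC, a member of the ribosome biogenesis list, stood at -0.56. In the antigen presentation list, the peptide transporter subunits TAP1 and TAP2 stood at 0.45 and 0.49, TAPBP at 0.73 and PSMB8 at 0.65, while B2M, the light chain of class I molecules, stood at 0.17 and was not called.

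Copy number differences between the cell populations were considered as a hypothesis, since selected populations of one line could differ by whole chromosome segments. The test looked for runs of 20 neighbouring bright genes that moved together beyond 0.42, the 95th percentile of the largest run in 1000 shuffled gene orders. Among 530 runs, 0 exceeded it, and the largest rise and fall were 0.37 and -0.34 relative to the median of all genes. Segments shorter than such a run were not tested, and a shift of a whole run smaller than 0.42 could not be detected.

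Bright genes whose probes belong to the A_33 naming series of the array had 289 rises of at least 2-fold among 3781 genes, against 159 among 6188 in the A_23 series; the difference was not tested.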
